A study of Mus musculus with 9 samples.

How the data were processed

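Spinal cord RNA-seq of 9 mouse libraries in 3 groups of 3 (saline, control ASO, C9orf72 ASO) was analysed from the table the authors deposited. Per the labels' protocols, total RNA was extracted with Trizol and strand-specific libraries were made. Adapters were removed with cutadapt 1.2.1 and reads aligned with GSNAP to the mouse build mm9, per the submitters' processing notes. The read counter, the gene annotation and the rule that chose the 14831 genes are not given in the sources used here. The values were taken as RPKM made by the authors. The deposited header names no unit, and the unit was read from the values. For short RNA genes (up to 350 bases) the product of value and exon length fell on multiples of 1 step per library, with 72.7% to 89.2% within 0.1 of a whole read.

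That step gives the depth, 90.4 to 123.7 M reads per library. Each value under 0.5 RPKM stood at 0.1 in the table (5160 values, 3.87%); 67 genes were at this floor in all libraries and 13817 in none. At the threshold of 0.5 RPKM a kilobase of transcript held 45.2 to 61.8 reads, so that the floor set the limit for low genes before depth did. Gene symbols came from a reference table that matched 14321 of 14831 Ensembl gene IDs and left 510 without a name. No genomic positions are given, because the reference in use was GRCm38 and the authors used mm9. An unnamed gene, ENSMUSG00000090378, held 18.99% to 23.37% of the RPKM sum of each library, and 16 genes shared all their values with another gene. No 2 libraries had identical values, and correlations between libraries were 0.9917 to 0.9968 within groups and 0.9913 to 0.997 between groups.

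Differences between groups were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend and robust estimation, statmod 1.5.0) on log2(RPKM + 0.1), in 1 fit of the 9 libraries. Genes with at least 0.5 RPKM in at least 3 libraries were tested (14430, with 401 removed), no further scaling was applied, and the threshold was a Benjamini-Hochberg adjusted p under 0.05. The pseudocount makes a fold change on this scale understate the change of low genes, while the replacement of values under 0.5 by 0.1 overstates it for genes that reach the floor. Mycn against the control ASO was at -1.95, and at -0.36 with floor values raised to 0.5 RPKM. Where all libraries of a group were at the floor, the fold was given as a bound against 0.5 RPKM. Such a group adds no spread to the fit, also with floor values raised, so that the p of these genes may be too small. The comparisons were C9orf72 ASO against control ASO, against saline and against both control groups (the mean of their means), and control ASO against saline. The table holds RPKM and not read counts, so the limma test planned for such values was used.

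Lists of genes (33 in all, 32 with at least 5 tested members) for cell types, pathways and complexes of the spinal cord, and the tests, groups and alternatives, were fixed before the data were examined. Lists were tested with camera (correlation preset at 0.01, then estimated) and fry, adjusted over lists within each comparison. The median, the mean and the direction of camera had the same sign in each called list. The genes named were the target and, among genes past the threshold whose libraries did not overlap, up to 12 with the highest and 12 with the lowest fold change. Where under 10 passed, the genes with the smallest p up to 10 were added. From each list came the members past the threshold (at most 4) or else the 2 with the smallest p. Predicted genes were named only among the 4 smallest p. A fixed set was named in any case (Smcr8, Wdr41, Gfap, Aif1, Chat, Mbp, Sqstm1, Lamp1, Rnaseh1, Grn, Tardbp and Sod1). Aif1 was not among the genes tested. Lamp1 (log2 fold change 0.14, adjusted p = 0.396), Rnaseh1 (0.04, adjusted p = 0.845) and Grn (0.07, adjusted p = 0.636) did not pass against the control ASO. Gm3852, single microglia genes and further list members were named after their values were seen.

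The test was tested on simulated data for C9orf72 ASO against control ASO, 14430 genes with 200 changed, drawn from genes with a mean of at least 1 RPKM. It called 36.6% of genes changed 1.25-fold, 78.4% of those changed 1.5-fold, 97.6% of those changed 2-fold and 100% of those changed 4-fold, and 6.1% of its calls were unchanged genes. Without any change it called 0.1 genes on average and at most 1 in 20 draws. These simulated libraries had independent genes and no shared trends, so that the rates of false calls may not hold for the real libraries. The shares of changes called may be too high for them as well. Genes under 1 RPKM were not among the changed ones, and the Benjamini-Hochberg threshold is easier to pass with 200 changed genes than with few. Alternatives covered another test setting, filter, pseudocount, scaling, threshold, samples in the fit, list test and each library left out in turn. Chosen after seeing the data were floor values raised to 0.5 RPKM, only genes with no library at the floor, and the removal of per-library trends with transcript length and GC content. That removal used natural splines with 5 degrees of freedom each, over the 13970 tested genes (96.8%) with a reference transcript. On simulated data with such trends it raised the share of 1.5-fold changes called from 54.5% to 84.5% (13720 genes, 200 changed, with 6 and 9 false calls). The planned count-based tests and scalings were not run. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.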

Results

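RNA was sequenced from the spinal cord of wild-type female C57Bl/6 mice aged 10 weeks that had received 10 µl into the right lateral ventricle of the brain 2 weeks before. Antisense oligonucleotides (ASOs) are short modified nucleic acid strands that pair with a chosen RNA and lower its level. Of 9 strand-specific libraries, 3 came from mice given saline, 3 from mice given 500 µg of a control ASO and 3 from mice given 500 µg of an ASO against C9orf72. C9orf72 is the gene whose repeat expansion is a common inherited cause of amyotrophic lateral sclerosis and frontotemporal dementia, and the design asks what loss of its function does in the spinal cord. The authors' table gave 14831 genes as RPKM, reads scaled to transcript length and library size, with each value under 0.5 replaced by 0.1. The step between low values implied 90.4 to 123.7 M reads per library, so that 0.5 RPKM stood for 45.2 to 61.8 reads per kilobase of transcript. Nothing in the labels says that the libraries of a group came from separate animals, and the p-values then measure the spread between these samples.

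C9orf72 (ENSMUSG00000028300), the target, was measured first. Its level was 11.1 ± 0.537 RPKM (SD, n = 3) after saline, 11.2 ± 0.549 RPKM after the control ASO and 3.07 ± 0.359 RPKM after the C9orf72 ASO. The C9orf72 ASO libraries held 27.5% ± 3.22 of the mean of the control ASO libraries and 27.6% ± 3.23 of the mean of the saline libraries. On the log2(RPKM + 0.1) scale C9orf72 fell by 1.84 against the control ASO (SE 0.08, adjusted p = 1.8e-06, limma), and the 3 values lay below the other 6 (exact permutation p = 0.0119, two-sided, the smallest that 84 splits allow). The control ASO left C9orf72 at a log2 fold change of 0.01 against saline (adjusted p = 0.989, limma). Smcr8 and Wdr41, whose proteins form a complex with that of C9orf72, had log2 fold changes of -0.15 (SE 0.10, adjusted p = 0.49) and 0.05 (SE 0.05, adjusted p = 0.694) against the control ASO and did not pass the threshold.

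**Figure D1:**
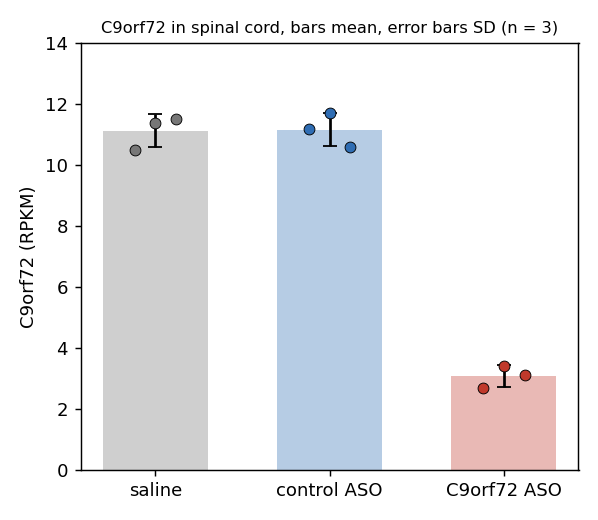
C9orf72 level in RPKM (vertical axis, linear from 0) in each spinal cord library of the 3 groups; bars are group means, error bars SD (n = 3) and dots single libraries. The C9orf72 ASO libraries lie between 2.68 and 3.4 RPKM, the other 6 between 10.5 and 11.7 RPKM.

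Against the control ASO, the comparison that separates lowering of the target from the injection of an oligonucleotide, 10 of 14430 genes passed the threshold, 5 higher and 5 lower. Tppp, which encodes a microtubule-binding protein of oligodendrocytes, fell from 552 ± 12.1 RPKM to 328 ± 13.7 RPKM (SD, n = 3; log2 fold change -0.75, SE 0.07, adjusted p = 8.3e-04). AA474408 rose from 1.69 ± 0.365 to 5.91 ± 1.48 RPKM (log2 fold change 1.74, SE 0.17, adjusted p = 0.00115). Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, rose from 874 ± 104 to 2730 ± 835 RPKM, a log2 fold change of 1.60 (SE 0.19, adjusted p = 0.00944). Its mean after the C9orf72 ASO was above that of the myelin gene Mbp over all libraries (2196.9 RPKM). Whether all reads counted for Lars2 came from the mRNA of this enzyme was not tested. Ccn1, a secreted matrix protein gene, and Btg2, an antiproliferative gene, both of the immediate early list, rose by log2 fold changes of 1.18 (SE 0.16, adjusted p = 0.022) and 0.84 (SE 0.11, adjusted p = 0.018). The list as a whole was not called by camera against the control ASO (median -0.09, adjusted p = 0.638) or both control groups (median -0.02, adjusted p = 0.0798). Capn11, a calpain protease gene, was at the floor in each C9orf72 ASO library and at 2.42 ± 0.889 RPKM after the control ASO, at least 4.84-fold lower (adjusted p = 5.8e-04). The neutrophil gene S100a9 was at least 5.13-fold lower (2.56 ± 1.08 RPKM after the control ASO, adjusted p = 0.00115), and it was at the floor after saline as well. Mycn, a transcription factor gene, was at least 1.34-fold lower (0.672 ± 0.0317 RPKM after the control ASO, adjusted p = 0.0349), a call that ended when floor values were raised to 0.5 RPKM. An unnamed gene, ENSMUSG00000078499, was the remaining one that rose.

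The calls of C9orf72, Tppp, AA474408 and Capn11 held in each of the 9 fits that left out 1 library. The call of Lars2 ended without control ASO replicate 1 (adjusted p = 0.0673), control ASO replicate 2 (0.0532) or C9orf72 ASO replicate 2 (0.0677), and with only the groups compared (0.0873). Ccn1 missed the threshold without control ASO replicate 1 (0.051) or 2 (0.0704) and without C9orf72 ASO replicate 1 (0.132) or 2 (0.0772), and Btg2 without control ASO replicate 1 (0.0774) or 3 (0.0697) or C9orf72 ASO replicate 2 (0.0677). Ccn1 was also lost in limma without trend and robust estimation (adjusted p = 0.0759), where the other 9 calls held. Mycn held only without C9orf72 ASO replicate 3. Its adjusted p reached 0.132 without control ASO replicate 2 and was 0.0873 with only the groups compared. ENSMUSG00000078499 was lost without control ASO replicate 1 (0.0892) or 3 (0.103) and without C9orf72 ASO replicate 1 (0.151) or 2 (0.0772). Without C9orf72 ASO replicate 3 the count was 27, with the 10 genes among them. At an unadjusted p under 0.05 lay 2034 genes (14.1%), and in 3171 genes (22%, where chance gives 10%) the libraries of both groups did not overlap.

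Of 32 gene lists fixed before the data were examined and large enough to test, 14 were called against the control ASO by camera with a preset correlation of 0.01, 10 higher and 4 lower. The homeostatic microglia list rose by a median log2 fold change of 0.18 over 19 genes (adjusted p = 8.5e-07), and by 0.09 without C9orf72 ASO replicate 1. The activated microglia list rose by 0.17 over 21 genes (adjusted p = 3.6e-04) and the list of complement and cytokine genes by 0.13 over 14 genes (adjusted p = 0.00551). Each of these had an adjusted p = 0.536 with an estimated correlation, and no list passed that way. No member of the homeostatic list passed over all genes, and 8 were higher adjusted over the list alone, among them C1qa, C1qb and C1qc of complement, Trem2 and its adaptor Tyrobp, P2ry12 and Fcrls. Among activated microglia genes Ctsd, Cd68, Lyz2 and Gpnmb passed adjusted over the list alone. The lists of ribosomal proteins (76 genes, median 0.23, adjusted p = 3.2e-23), oxidative phosphorylation (78 genes, 0.14, adjusted p = 2.1e-12) and histones (32 genes, 0.25, adjusted p = 1.2e-05) rose too. So did those of ependyma and choroid plexus (14 genes, 0.27, adjusted p = 0.00171), reactive astrocytes (25 genes, 0.11, adjusted p = 0.00627) and the lysosome (48 genes, 0.05, adjusted p = 0.00852). Each of these 6 lists had an adjusted p = 0.536 with an estimated correlation. The histone median was 0.07 without C9orf72 ASO replicate 3, 0.13 without control ASO replicate 2 and 0.40 without C9orf72 ASO replicate 1. No ribosomal protein gene passed over all genes and 29 were higher adjusted over the list alone. The interferon list rose by a median of 0.05 (adjusted p = 0.0396, and adjusted p = 0.759 with an estimated correlation), with Mx2 at 0.43 (SE 0.14, adjusted p = 0.259). The interferon call ended without saline replicate 2, control ASO replicate 2 or 3 or C9orf72 ASO replicate 1 or 3 (highest adjusted p = 0.257). It ended too with quantile normalization (adjusted p = 0.0862), with only genes at the floor in no library (0.0552) and with length and GC trends removed (median 0.03, adjusted p = 0.244). Its median was 0.10 without control ASO replicate 1 or C9orf72 ASO replicate 2, 0.08 without C9orf72 ASO replicate 3 and 0.03 without control ASO replicate 2, and that of the lysosome 0.03 without C9orf72 ASO replicate 1.

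Against the control ASO the neuron list fell by 0.10 on the log2 scale (34 genes, adjusted p = 0.00171, and adjusted p = 0.536 with an estimated correlation). It had 0 members past the threshold in limma, over all genes or adjusted over the list alone, and 6 at an unadjusted p under 0.05. Syn1 was at -0.32 (SE 0.09, adjusted p = 0.237). The list of endothelium and mural cells fell by 0.15 (26 genes, adjusted p = 0.00968, and adjusted p = 0.759 with an estimated correlation). The list of the unfolded protein response fell by 0.07 (28 genes, adjusted p = 0.0202, and adjusted p = 0.7 with an estimated correlation). The list of blood and infiltrating leukocytes, 5 of whose 9 genes are haemoglobin and heme synthesis genes of red blood cells, fell by 0.37 (9 genes, adjusted p = 0.013, and adjusted p = 0.551 with an estimated correlation), with S100a8 and S100a9 lower adjusted over the list alone. S100a8 and S100a9 leave the list, by the filter, when any control ASO library is left out. Over the 7 other genes, none at the floor in any library, the median was -0.24 with all libraries (adjusted p = 0.61), and the call ended. Without control ASO replicate 1, whose haemoglobin transcript Hba-a1 stood at 1060 RPKM against 255 to 451 RPKM in the other libraries, the median of the same 7 genes was 0.22 (adjusted p = 0.128). The call of the list also ended without control ASO replicate 2 (7 genes, adjusted p = 0.507) or C9orf72 ASO replicate 2 (median -0.13, adjusted p = 0.0766), and its median was -0.63 over 7 genes without control ASO replicate 3. The endothelial call ended without control ASO replicate 1, control ASO replicate 2 or C9orf72 ASO replicate 2 (highest adjusted p = 0.218). That on the unfolded protein response ended without control ASO replicate 2 or C9orf72 ASO replicate 1 or 2 (highest adjusted p = 0.224). The unfolded protein median was -0.04 without control ASO replicate 2 or C9orf72 ASO replicate 1 and -0.11 without C9orf72 ASO replicate 3. Fold changes ran against transcript length in this comparison (r = -0.41 across 13423 genes, which are not independent replicates), with a median of 0.08 in the fifth of genes with the shortest transcripts and -0.09 in that with the longest. The endothelial median was -0.28 without control ASO replicate 3 and -0.08 without control ASO replicate 1. With length and GC trends removed, the medians were 0.12 for ribosomal proteins (adjusted p = 1.0e-12), 0.04 for oxidative phosphorylation (adjusted p = 0.00822) and 0.14 for histones (adjusted p = 0.00146). They were 0.17 for ependyma and choroid plexus (adjusted p = 0.0378) and 0.06 for reactive astrocytes (adjusted p = 0.0153). With an estimated correlation these 5 lists then had an adjusted p between 0.466 and 0.778.

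Several groups of interest for motor neuron disease did not move as lists against the control ASO. The list of 37 genes linked to amyotrophic lateral sclerosis and frontotemporal dementia had a median of -0.03 (adjusted p = 0.384). Its member Taf15 was lower adjusted over the list alone (43.6 against 55.4 RPKM, log2 fold change -0.35, SE 0.07, adjusted p = 0.178 over all genes). Tardbp and Sod1 stood at 0.01 (SE 0.06, adjusted p = 0.947) and 0.06 (SE 0.11, adjusted p = 0.827). The 42 autophagy genes had a median of -0.02 (adjusted p = 0.638), with Sqstm1 at 0.02 (SE 0.08, adjusted p = 0.915). The motor neuron list had a median of -0.04 over 19 genes (adjusted p = 0.638). Chat, the gene of its acetylcholine-synthesising enzyme, had a log2 fold change of -0.05 (SE 0.09, adjusted p = 0.839), while the peptide gene Calca was at 0.62 (SE 0.13, adjusted p = 0.171) and passed adjusted over the list alone. The oligodendrocyte list, which holds the myelin gene Mbp at 0.05 (SE 0.10, adjusted p = 0.861), had a median of 0.02 over 26 genes (adjusted p = 0.571). Gfap, the astrocyte filament gene, was at 0.13 (SE 0.11, adjusted p = 0.595).

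Against saline, the second control, 10 of 14430 genes passed the threshold, 5 higher and 5 lower. Tppp fell from 562 ± 34 RPKM (SD, n = 3; log2 fold change -0.78, SE 0.07, adjusted p = 9.0e-04). AA474408 rose by 1.63 (SE 0.17, adjusted p = 0.00366), Ccn1 by 1.24 (SE 0.16, adjusted p = 0.0211) and Btg2 by 0.79 (SE 0.11, adjusted p = 0.031). A pair of myeloid genes rose. Lyz2, which encodes lysozyme and has a near-identical neighbour, Lyz1, so that its value is uncertain, rose from 2.79 ± 0.515 to 6.02 ± 0.95 RPKM (log2 fold change 1.09, SE 0.14, adjusted p = 0.0176). Tyrobp rose from 12.9 ± 1.6 to 20.7 ± 1.24 RPKM (log2 fold change 0.68, SE 0.10, adjusted p = 0.031). Ide, the insulin-degrading enzyme gene, fell from 17.1 ± 1.63 to 11.9 ± 0.678 RPKM (log2 fold change -0.51, SE 0.07, adjusted p = 0.031) and stood at 11.7 ± 0.254 RPKM after the control ASO. At the floor after the C9orf72 ASO were Capn11, at least 2.41-fold lower (1.21 ± 0.475 RPKM after saline, adjusted p = 0.00691), and Piezo1, a mechanosensitive channel gene, at least 1.38-fold lower (0.691 ± 0.153 RPKM, adjusted p = 0.0449). Both calls ended with floor values raised to 0.5 RPKM (adjusted p = 0.179 and 0.262) and with a pseudocount of 1 (0.0767 and 0.0565). In limma without trend and robust estimation 5 of the 10 calls held, and those of Btg2 (adjusted p = 0.0571), Ccn1 (0.0644), Lyz2 (0.0571), Tyrobp (0.0925) and Ide (0.0882) ended. With only the groups compared 4 held, and Btg2, Lyz2, Tyrobp and Capn11 (0.0852 each), Ide (0.116) and Piezo1 (0.145) did not. With median log ratio scaling Ide (0.059) and Piezo1 (0.0506) missed the threshold. The calls of C9orf72, Tppp, AA474408 and Capn11 held when any 1 library was left out, and these 4 genes were the ones left without saline replicate 2, without C9orf72 ASO replicate 1 or without C9orf72 ASO replicate 2. Tyrobp reached an adjusted p = 0.118 without saline replicate 2 and 0.104 without saline replicate 3, and the call of Ide ended in 6 of the 9 such fits (highest adjusted p = 0.114, without saline replicate 2). Without saline replicate 1 Ccn1 was at 0.0529, Btg2 at 0.0591 and Piezo1, which held in 1 of the 9 fits, at 0.147 (highest 0.168). Without control ASO replicate 3 the count was 16, and without C9orf72 ASO replicate 3 it was 54, the 10 included.

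By camera with the preset correlation, 9 of 32 lists were called against saline, 8 higher and 1 lower. The homeostatic microglia list rose by a median of 0.24 (adjusted p = 2.2e-07, and adjusted p = 0.472 with an estimated correlation). Its median was 0.09 without C9orf72 ASO replicate 1. It had 1 member past the threshold over all genes and, adjusted over the list alone, 9 higher and 1, Selplg, lower. The activated microglia list rose by 0.18 (adjusted p = 8.4e-08, and adjusted p = 0.472 with an estimated correlation), led by Lyz2, with Clec7a and Cd68 also past adjusted over the list alone, and by 0.28 without saline replicate 1. Immediate early genes rose by a median of 0.04 over 23 genes (adjusted p = 0.00173, and adjusted p = 0.725 with an estimated correlation). Of these, 5 were higher adjusted over the list alone, Ccn1 and Btg2 over all genes as well. The call ended without C9orf72 ASO replicate 3 (median 0.02, adjusted p = 0.0695). The median was 0.12 without C9orf72 ASO replicate 1, 0.07 without saline replicate 1, 0.01 without saline replicate 2 and 0.02 without saline replicate 3. The list of endothelium and mural cells, which holds the vessel genes Flt1 and Rgs5, fell by 0.43 (adjusted p = 1.3e-12, and adjusted p = 0.472 with an estimated correlation). Of its genes, 19 of 26 were lower adjusted over the list alone and 0 over all genes in limma, with 20 lower at an unadjusted p under 0.05. Ribosomal protein genes had a median of 0.13 (adjusted p = 4.1e-11, and adjusted p = 0.827 with an estimated correlation), and this call ended without saline replicate 2 (median 0.00, adjusted p = 0.31). The ribosomal median was 0.07 with length and GC trends removed (adjusted p = 1.6e-06, and adjusted p = 0.736 with an estimated correlation). That of immediate early genes was then 0.09 (adjusted p = 5.9e-05, and adjusted p = 0.442 with an estimated correlation). At an unadjusted p under 0.05 lay 2013 genes (14%), and in 2599 genes (18%, where chance gives 10%) the libraries did not overlap.

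The control ASO was set against saline to show what an oligonucleotide without the target does, and 1 of 14430 genes passed. S100a9, which encodes a calcium-binding protein abundant in neutrophils, was at 3.68, 2.48 and 1.52 RPKM in the 3 control ASO libraries and at the floor in the 3 saline libraries, at least 5.13-fold higher (adjusted p = 0.00574, limma). The saline and C9orf72 ASO libraries, all at the floor for S100a9, added no spread to the fit, so that this p may be too small. Its partner S100a8 was at least 3.19-fold higher (1.59 ± 0.928 RPKM, SD, n = 3) and did not pass over all genes (adjusted p = 0.225), though both passed adjusted over the leukocyte list alone. S100a9 fell under the filter, and was not tested, when any of the control ASO libraries was left out. Ide was lower in the control ASO libraries by a log2 fold change of -0.54 (SE 0.07) without passing (adjusted p = 0.0883). Likewise lower without passing were Btaf1 at -0.34 (SE 0.07, adjusted p = 0.77) and Dao, which encodes D-amino acid oxidase, at -0.35 (SE 0.08, adjusted p = 0.77). Fam129c, Stoml3 and Lrrc43 were at the floor after the control ASO and between 0.648 and 0.69 RPKM on average after saline (adjusted p = 0.132 each). With length and GC trends removed, Ide (adjusted p = 0.00187, up to 0.449 over its alternatives) and Btaf1 (adjusted p = 0.0113, up to 0.987) passed with S100a9. Over the alternatives the count ran from 0 to 9. At an unadjusted p under 0.05 lay 772 genes (5.3%).

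Lists called between control ASO and saline numbered 10 of 32, 5 higher and 5 lower, each with an adjusted p = 0.749 with an estimated correlation. Endothelium and mural cell genes fell by a median of 0.26 (adjusted p = 6.3e-10), and their median was -0.16 without control ASO replicate 3. Ribosomal protein genes fell by 0.11 (adjusted p = 8.7e-06, a call that ended without saline replicate 1 or 3, highest adjusted p = 0.229). The ribosomal median was -0.06 without saline replicate 1, -0.05 without saline replicate 3 and -0.23 without saline replicate 2. It was -0.03 with length and GC trends removed (adjusted p = 0.00172, and adjusted p = 0.882 with an estimated correlation). The leukocyte list rose by 0.53 (adjusted p = 1.5e-05), and S100a8 and S100a9 again leave it when a control ASO library is left out. Over the 7 other genes the median was 0.53 with all libraries (adjusted p = 0.0659), a call that ended, and -0.06 without control ASO replicate 1, the library with the high haemoglobin transcripts (adjusted p = 0.911). Over the same genes it was 0.68 without control ASO replicate 2 (adjusted p = 0.0829) and 0.94 without control ASO replicate 3. Immediate early genes rose by 0.11 (adjusted p = 0.00232), a call that ended without saline replicate 2 (median 0.03, adjusted p = 0.0765) or control ASO replicate 2 (median 0.07, adjusted p = 0.0806). The homeostatic microglia list had a median of -0.01 (adjusted p = 0.818) and the activated list one of 0.06 (adjusted p = 0.0758), with Clec7a and Lyz2 higher adjusted over the list alone. Once length and GC trends were removed, the activated list had a median of 0.09 (adjusted p = 0.0462, and adjusted p = 0.765 with an estimated correlation).

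Set against both control groups together, the C9orf72 ASO libraries had 25 of 14430 genes past the threshold, 11 higher and 14 lower. Tppp fell by 0.76 on the log2 scale (SE 0.06, adjusted p = 2.3e-04). AA474408 rose by 1.68 (SE 0.14, adjusted p = 4.5e-04), Lars2 by 1.39 (SE 0.17, adjusted p = 0.00797), Ccn1 by 1.21 (SE 0.14, adjusted p = 0.00685) and Btg2 by 0.81 (SE 0.09, adjusted p = 0.00685). Of the genes of microglia and myeloid cells, Lyz2 rose by 0.83 (SE 0.12, adjusted p = 0.024) and Tyrobp by 0.62 (SE 0.08, adjusted p = 0.0173). C1qb, a chain of the first complement component, rose by 0.46 (SE 0.07, adjusted p = 0.0402; 35.5 ± 0.533 RPKM against 26.3 ± 3.66 after saline and 25.5 ± 1.05 after the control ASO). Rmrp, the RNA of a mitochondrial RNA processing ribonuclease, rose by 0.96 (SE 0.16, adjusted p = 0.0419), Ppp1r17, a phosphatase inhibitor gene, by 0.68 (SE 0.11, adjusted p = 0.0402) and Rex2 by 0.57 (SE 0.09, adjusted p = 0.042). ENSMUSG00000078499 rose too (adjusted p = 0.0114). Smaller decreases met the threshold for Hipk2, a protein kinase gene (log2 fold change -0.44, adjusted p = 0.0293), for the neuronal splicing factor gene Nova2 (-0.35, adjusted p = 0.042) and Ankrd52 (-0.31, adjusted p = 0.0294). The same held for the amino acid transporter gene Slc7a5 (-0.34, adjusted p = 0.0402) and the microtubule-regulating kinase gene Mark2 (-0.34, adjusted p = 0.046). Capn11, Mycn, Piezo1 and Kif26a, a kinesin gene, were at the floor in each C9orf72 ASO library, and Capn11 kept its call with floor values raised to 0.5 RPKM while the other three did not. S100a9, at the floor after saline too, was lower (adjusted p = 0.046), and so were Gm3852 (adjusted p = 0.024) and an unnamed gene, ENSMUSG00000069671.

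**Figure D2:**
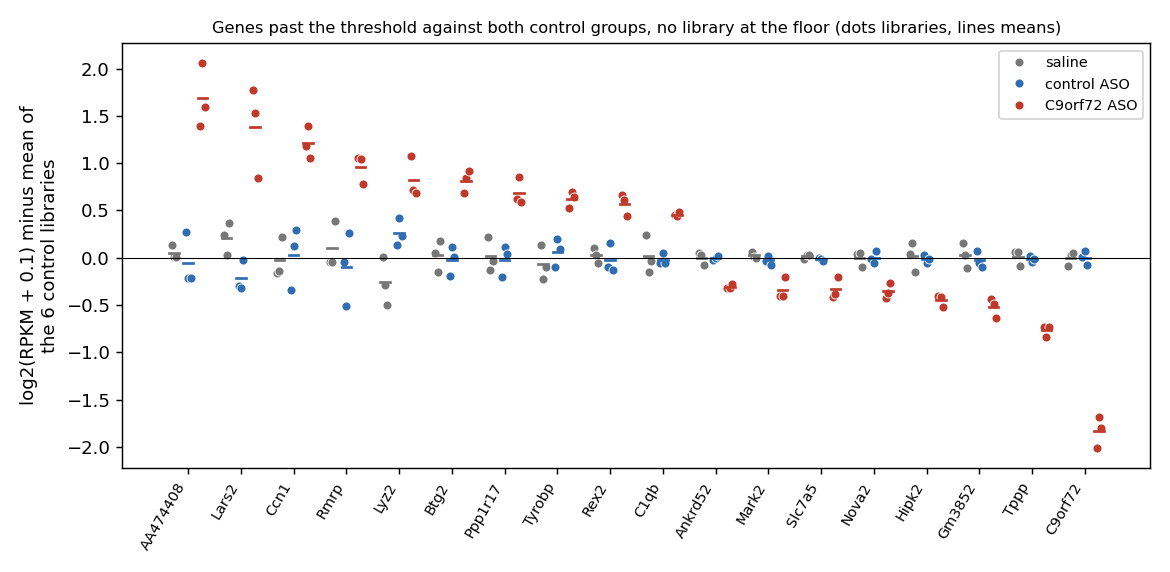
Each dot is a library: log2(RPKM + 0.1) minus the mean of the 6 control libraries (vertical axis) for the genes with a symbol that passed the threshold against both control groups and were at the floor in no library, ordered by log2 fold change; lines are group means. The C9orf72 ASO libraries lie apart from the 6 control libraries for each gene shown, by 1.68 for AA474408 and -1.83 for C9orf72 on average.

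In the comparison with both groups the calls of C9orf72, Tppp, AA474408, Btg2 and Capn11 held when any 1 library was left out. Lars2 lost its call without saline replicate 2 (adjusted p = 0.0589), Ccn1 without C9orf72 ASO replicate 1 (0.0515) and Tyrobp without C9orf72 ASO replicate 1 (0.0637) or 2 (0.0786). The calls of Lyz2, Rmrp, Ppp1r17, Rex2, C1qb, Hipk2, Nova2, Slc7a5, Mark2 and Ankrd52 ended without C9orf72 ASO replicate 1, without C9orf72 ASO replicate 2, without control ASO replicate 1 and in up to 5 of the other 6 such fits. Their highest adjusted p lay between 0.142 for Hipk2 and 0.317 for Mark2. Mycn and Piezo1 missed the threshold without saline replicate 2, control ASO replicate 1 or C9orf72 ASO replicate 1 (highest adjusted p = 0.0691). Kif26a held only without saline replicate 3 or C9orf72 ASO replicate 3 (highest 0.0876). S100a9, tested in 6 such fits, held only without C9orf72 ASO replicate 3 (highest 0.229). Its call ended as well with raised floor values (adjusted p = 0.0587) and with a pseudocount of 1 (0.0635) or 0.01 (0.0729). Gm3852 was lost without saline replicate 2, control ASO replicate 1 or 2 or C9orf72 ASO replicate 1 or 2 (highest 0.0786). ENSMUSG00000069671 held only without saline replicate 3, control ASO replicate 2 or C9orf72 ASO replicate 3 (highest 0.259), and ENSMUSG00000078499 was lost without C9orf72 ASO replicate 1 (0.0779). In limma without trend and robust estimation 15 of the 25 calls held. Lost there were Lyz2, Tyrobp, C1qb, Rmrp, Ppp1r17, Hipk2, Nova2, Slc7a5, Mark2 and ENSMUSG00000069671, with an adjusted p between 0.0589 for Tyrobp and 0.111 for Rmrp. Mark2 missed the threshold with median log ratio scaling (0.0502) and Nova2 with quantile normalization (0.053). Without C9orf72 ASO replicate 1 7 genes passed, without saline replicate 2 9, and without control ASO replicate 1 13. Without C9orf72 ASO replicate 3 139 passed, 23 higher and 116 lower, the 25 among them. With length and GC trends removed 31 genes passed, 19 of them shared, and the calls of Nova2 (adjusted p = 0.123), Rmrp (0.0829), Ankrd52 (0.132) and Mark2 (0.0829) ended. Over their alternatives the adjusted p ran from 0.0249 to 0.31 for Nova2, 0.0188 to 0.283 for Rmrp, 0.0282 to 0.235 for Ankrd52 and 0.0157 to 0.317 for Mark2.

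Genes of microglia, the resident immune cells of the spinal cord, were compared as a pair of lists. The homeostatic microglia list rose by a median of 0.27 against both groups (adjusted p = 9.2e-08, and adjusted p = 0.482 with an estimated correlation). Tyrobp and C1qb were past the threshold over all genes and, 9 genes were higher and 1 lower adjusted over the list alone. Trem2 was at 0.48 (SE 0.09, adjusted p = 0.0657), Fcrls at 0.61 (SE 0.10, adjusted p = 0.0531), C1qa at 0.39 (SE 0.11, adjusted p = 0.159) and P2ry12 at 0.28 (SE 0.05, adjusted p = 0.0733). In the same list the microglial receptor and marker genes Csf1r (0.01, SE 0.06), Tmem119 (0.03, SE 0.08), Sall1 (0.00, SE 0.06) and Siglech (0.07, SE 0.07) stood near 0, and Selplg was at -0.23 (SE 0.06, adjusted p = 0.162). The activated microglia list rose by 0.21 (adjusted p = 9.6e-07, and adjusted p = 0.482 with an estimated correlation), with Lyz2 past over all genes and Ctsd, Cd68, Lgals3, Lyz2 and Gpnmb adjusted over the list alone. Both microglial calls held when any 1 library was left out, and the homeostatic median was 0.11 without C9orf72 ASO replicate 1, whose omission moved it most. The homeostatic list's mean lay above those of the other 6 libraries in the 3 C9orf72 ASO libraries (difference 0.20, exact permutation p = 0.0119, two-sided, and 0.196 adjusted over 33 lists).

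**Figure D3:**
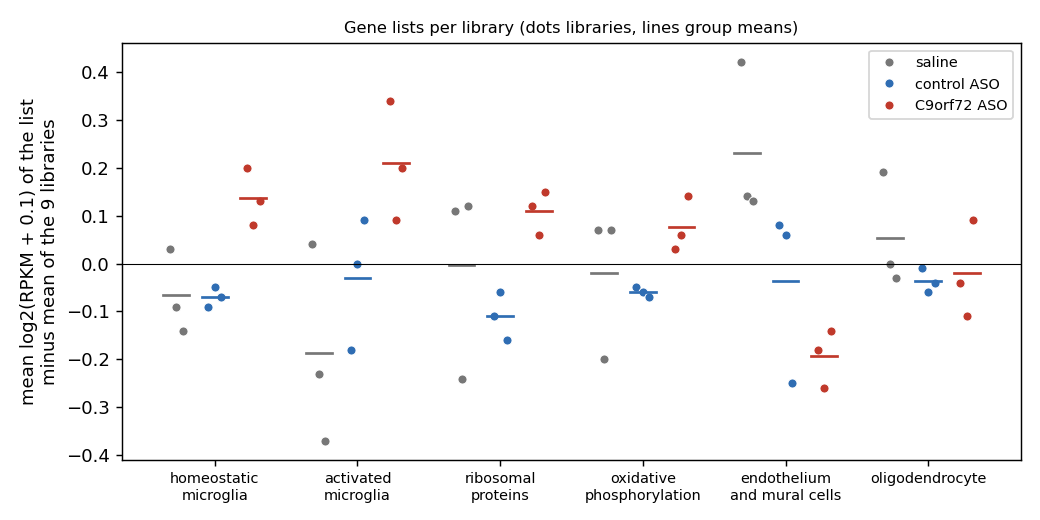
Mean log2(RPKM + 0.1) of the genes of 6 lists in each library, minus the mean of the 9 libraries (vertical axis); dots are libraries and lines group means. For homeostatic microglia the C9orf72 ASO libraries lie between 0.08 and 0.2 and the other 6 between -0.14 and 0.03, while for ribosomal proteins saline libraries span -0.24 to 0.12.

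Other lists moved against both control groups. Ribosomal protein genes rose by a median of 0.18 (adjusted p = 9.8e-20, and adjusted p = 0.684 with an estimated correlation). Oxidative phosphorylation genes rose by 0.12 (adjusted p = 4.1e-13, and adjusted p = 0.684 with an estimated correlation). Without saline replicate 2 these medians were 0.11 and 0.07. Fold changes in this comparison ran against transcript length (r = -0.32) and GC content (r = -0.30) across 13423 genes. Endothelium and mural cell genes fell by 0.28 (adjusted p = 8.6e-08, and adjusted p = 0.664 with an estimated correlation). Of these, 10 of 26 were lower adjusted over the list alone and 0 over all genes in limma, with 15 lower at an unadjusted p under 0.05. The mean of this endothelial list differed by -0.29 (exact permutation p = 0.0952, two-sided, and 0.294 adjusted over 33 lists). Relative to the mean of the 9 libraries, control ASO replicate 3 was at -0.25 and the C9orf72 ASO libraries between -0.26 and -0.14, so that the groups overlapped. Reactive astrocyte genes rose by 0.04 (adjusted p = 0.00348, and adjusted p = 0.664 with an estimated correlation) and complement and cytokine genes by 0.09 (adjusted p = 0.00258, and adjusted p = 0.482 with an estimated correlation). The reactive astrocyte median was 0.00 without saline replicate 2, 0.08 without saline replicate 1, 0.07 without saline replicate 3 and 0.09 without control ASO replicate 2 or C9orf72 ASO replicate 3. It was also 0.07 with length and GC trends removed (adjusted p = 0.00809, and adjusted p = 0.574 with an estimated correlation). That of complement and cytokine genes was 0.15 without C9orf72 ASO replicate 2. The neuron list fell by 0.07 (adjusted p = 0.0251, and adjusted p = 0.733 with an estimated correlation). This call ended without saline replicate 3, control ASO replicate 3, C9orf72 ASO replicate 1 or C9orf72 ASO replicate 3 (highest adjusted p = 0.228; median -0.04 without C9orf72 ASO replicate 1).

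The comparisons with control ASO and with saline, which share the C9orf72 ASO libraries, had 6 genes in common in the same direction: AA474408, Btg2 and Ccn1 higher, and C9orf72, Capn11 and Tppp lower. Simulated groups without any change gave 0.05 on average and at most 1 in 100 draws, independent lists of these sizes would share 0.0017 in each direction, and part of the excess may come from the shared libraries. The effects of both ASOs against saline, which share the saline libraries, correlated across 14430 genes (Pearson r = 0.41, Spearman rho = 0.35), below the 0.50 (0.44 to 0.55) of simulated groups without any change. Their covariance was 0.0175 against 0.0172 in the simulation, a difference of 0.000252. These simulations drew each gene in each library independently, without the length and GC trends of the real libraries. Their ranges may therefore be too narrow. With 1 library left out r ran from 0.33 to 0.53, so that a value below the simulated range decides nothing.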

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

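The alternatives chosen only after the data were seen are raised floor values, only genes with no library at the floor, and removal of length and GC trends. Of 46 gene results past the threshold, 14 kept direction and side under each of up to 22 alternatives, 32 lost their call in at least 1 and 0 reversed: C9orf72, AA474408 and Tppp kept theirs in the comparisons with each control group and with both. C9orf72 against the control ASO ran from -1.91 to -1.75 with 1 library left out. Without trend and robust estimation 19 genes passed against the control ASO and 9 between control ASO and saline, and 10 were shared by both control comparisons. Of the calls past the threshold it kept 9 of 10 against the control ASO, 5 of 10 against saline and 15 of 25 against both controls. Without a filter the counts were 16 and 5 and the correlation of ASO effects 0.44. A mean of at least 1 RPKM gave 0 genes between control ASO and saline, 39 against both controls and a correlation of 0.34. A pseudocount of 1 gave a correlation of 0.36, and a fit of only the groups compared 4 genes against saline. At an adjusted p of 0.10, 26, 48, 2 and 86 genes passed (control ASO, saline, control ASO against saline, both controls), with 19 shared; with at least a 1.5-fold change 16 passed against both. Raised floor values gave a correlation of 0.37, and genes with no library at the floor 0 genes between control ASO and saline, 39 against both and a correlation of 0.37. With length and GC trends removed 17, 20 and 3 genes passed, with 10 shared. With an estimated correlation 0, 0, 0 and 0 lists were called in these comparisons, and with fry 1, 1, 0 and 1, each the list around C9orf72. That list holds the target itself. Its median was 0.01 against the control ASO, 0.00 against saline and -0.00 against both controls. With 1 library left out the counts ran from 7 to 27 against the control ASO, 4 to 54 against saline, 0 to 2 between control ASO and saline, 7 to 139 against both and 4 to 22 shared. The correlation ran from 0.33 to 0.53, and lists called from 11 to 15, 6 to 11, 5 to 13 and 9 to 12. Of 44 list calls the direction of the test turned in 2, both for leukocytes without control ASO replicate 1, where S100a8 and S100a9 were not tested, and neither past the threshold there: their median ran from -0.63 to 0.22 against the control ASO and from -0.06 to 0.94 between control ASO and saline. In 4 other list calls the median alone changed sign, with the call lost: reactive astrocytes (-0.03) and histones (-0.03) against saline and splicing regulators between control ASO and saline (-0.01), each without saline replicate 2, and the lysosome against both controls without C9orf72 ASO replicate 1 (-0.01). Histones against saline were also at -0.05 without C9orf72 ASO replicate 3. The counts at another adjusted p or fold follow from that threshold; for the rest, the higher counts without C9orf72 ASO replicate 3 included, the cause was not tested. No paired analysis was possible because replicate numbers followed accession order and the labels carry none. The planned count-based tests and scalings were not run, since the values are not counts. The floor at 0.5 RPKM limits the low genes Mycn, Piezo1 and Kif26a, whose calls ended with raised floor values wherever they had passed, and so did those of S100a9 against both controls (adjusted p = 0.0587) and Capn11 against saline (0.179).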

Other observations

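The tests of transcript length and GC trends, of blood leukocytes, of the number of microglia and of oligodendrocytes were chosen only after the results were seen. A few gene groups were not described above. Genes of the circadian clock moved in both directions against saline, with 3 higher and 2 lower adjusted over the list alone (Ciart, Per3, Dbp, Nr1d1 and Arntl). Over all genes 0 passed in limma, with 6 higher and 2 lower at an unadjusted p under 0.05, and the list was not called (median 0.10, adjusted p = 0.0695). The list was called, once length and GC trends were removed, against saline (median 0.14, adjusted p = 0.00178, and adjusted p = 0.431 with an estimated correlation) and against both control groups (median 0.08, adjusted p = 0.0394, and adjusted p = 0.574 with an estimated correlation). Between control ASO and saline it was called (median 0.07, adjusted p = 0.0354, and adjusted p = 0.749 with an estimated correlation). That call ended without saline replicate 1 (adjusted p = 0.394) or 2 (0.0657) and without control ASO replicate 1 (0.0802) or 2 (0.15), and with quantile normalization (0.0597). The median ran from 0.03 to 0.09 with 1 library left out and was 0.11 with length and GC trends removed. With length and GC trends removed, Dbp, a clock output gene, passed against saline (log2 fold change 0.44, SE 0.05, adjusted p = 0.00953) and Arntl, its upstream activator, was lower (-0.33, SE 0.05, adjusted p = 0.0445). The same removal brought past the threshold Trem2 (0.53, SE 0.08, adjusted p = 0.0256), Lag3 (0.70, SE 0.11, adjusted p = 0.0256) and Taf15 (-0.34, SE 0.05, adjusted p = 0.0212) against both control groups. These genes were picked after their values were seen, and their adjusted p without the removal was 0.173 for Dbp, 0.0689 for Arntl, 0.0657 for Trem2 and Lag3 and 0.0923 for Taf15. Over all alternatives it ran from 0.00953 to 0.431 for Dbp, 0.0445 to 0.294 for Arntl, 0.0124 to 0.358 for Trem2, 0.0256 to 0.259 for Lag3 and 0.0212 to 0.279 for Taf15.

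Meningeal and fibroblast genes fell by a median of 0.14 in the control ASO libraries against saline (adjusted p = 0.0156, and adjusted p = 0.749 with an estimated correlation). This call ended without saline replicate 1 (median -0.07, adjusted p = 0.0841) or 2 (adjusted p = 0.0649) and without control ASO replicate 3 (median -0.08, adjusted p = 0.197). It ended too with only genes at the floor in no library (adjusted p = 0.0649). With length and GC trends removed the median was -0.09 (adjusted p = 0.037, and adjusted p = 0.765 with an estimated correlation). After the C9orf72 ASO the list had a median of -0.23 against saline (adjusted p = 0.0738), with Bgn and Lum lower adjusted over the list alone. That median was -0.14 with length and GC trends removed (adjusted p = 0.16). The oligodendrocyte precursor list had a median of -0.09 against both control groups (adjusted p = 0.0853), and of -0.02 with length and GC trends removed (adjusted p = 0.485).

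How often other splits of the libraries gave as many genes was counted. Against the control ASO, 1 of the 10 splits of the 6 libraries, the real one, gave 10 genes, and the highest other gave 3. Against saline it was 1 of 10, with 10 genes and 0 at the highest other. Between control ASO and saline 3 of 10 gave at least the real 1 gene, with 4 at the highest other. In these 3 comparisons the splits are too few for a share under 0.05. Against both control groups, a fit of 2 groups called 32 genes. Of the 84 splits 2 gave as many, the real one included, a share under 0.05. The other of these gave 114 genes, so that a split across the groups can exceed the real count. The real count takes in the target, which the ASO lowers by design, and the share does not speak for the other genes called. Of 100 drawn splits into 3 groups, 2 gave as many shared genes as the real 6, the real one included, with 7 at the highest other. That share is under 0.05, but the 6 include C9orf72 itself, and no count without the target was made. Chance is therefore not excluded for the other shared genes. For the number of lists called (12 in the 2-group fit), 17 of 84 splits gave as many, with 18 at the highest other, so that chance cannot be excluded. The other split with the most genes, 114, put saline replicate 2 with control ASO replicates 1 and 3, which points to a structure of the samples that crosses the groups. Of its genes 86 were lower and 28 higher in those 3 libraries, their median transcript was 1326 bases long against 3395 for all tested genes, and the split gave 0 genes with length and GC trends removed.

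Microglial genes were higher in the C9orf72 ASO libraries than in both control groups, by a median of 0.27 for the homeostatic list. Its mean had an exact permutation p = 0.0119 taken alone. Adjusted over 33 lists this was 0.196, so that variation between libraries cannot be excluded. The tables argue against length and GC trends, since the median was 0.18 with these removed, with an exact permutation p = 0.0119 for the list mean (camera adjusted p = 1.6e-09, and adjusted p = 0.388 with an estimated correlation). More microglia with unchanged transcripts per cell would move the 16 list genes above 5 RPKM alike, yet the SD of their fold changes, 0.24, was above the 0.19 of the highest other split (exact permutation p = 0.0119, with trends kept or removed, the smallest that 84 splits give). A contribution of blood leukocytes cannot be told apart from a microglial change. Of the 9 genes of their list 5 are red blood cell genes, so that its median of -0.11 decides nothing (bootstrap 95% interval over genes -1.43 to 0.08). S100a8 and S100a9 were at the floor in each C9orf72 ASO library. Also open and untested are an effect of lowering C9orf72 on part of the microglial genes and a response to the sequence of this ASO, since 1 ASO against C9orf72 was used.

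Ribosomal protein and oxidative phosphorylation genes were higher in the C9orf72 ASO libraries than in both control groups, by medians of 0.18 and 0.12. Differences between single libraries could give this pattern: as large a difference in the list mean came from 10 of 84 splits for ribosomal proteins (exact permutation p = 0.119) and 9 for oxidative phosphorylation (exact permutation p = 0.107). In the split of saline replicate 2 with control ASO replicates 1 and 3 the ribosomal median was -0.25. With length and GC trends removed the medians were 0.09 and 0.05, about as far from 0 as from their former values, so that trend and a change of these short transcripts cannot be told apart. An effect of the C9orf72 ASO on these genes stays open.

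Tppp, at -0.76 against both control groups, was the most abundant named gene past the threshold that fell. Fewer oligodendrocytes would lower their other transcripts about as far, but the oligodendrocyte list had a median of -0.04. The bootstrap 95% interval, -0.06 to 0.01, resampled genes and holds no variation between libraries. Relative to the mean of the 9 libraries, the list mean ran from -0.11 to 0.09 in the C9orf72 ASO libraries. In the others it ran from -0.06 to 0.19. Length and GC trends are argued against by a log2 fold change of -0.73 with these removed (adjusted p = 9.3e-05). Its decrease may then belong to C9orf72 lowering or to pairing of this ASO with Tppp RNA, a hypothesis that was not tested, because the sequence of the ASO is not given in the sources used here. Tppp differed by less than the spread between replicates between control ASO and saline (552 ± 12.1 and 562 ± 34 RPKM, SD, n = 3).

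The C9orf72 ASO libraries differed among themselves in their trend with GC content, with correlations of -0.42 and -0.50 for replicates 1 and 2 and 0.31 for replicate 3 across 13423 genes. Control ASO replicate 1 held Hba-a1 at 1060 RPKM, the other 8 libraries at 255 to 451 RPKM. S100a8 and S100a9 were above the floor in the 3 control ASO libraries and at the floor in the other 6.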
